A study of Homo sapiens with 24 samples.

How the data were processed

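HT-29 is a human colon cancer line of epithelial cells. Wild-type (WT) cells and cells in which the gene GPRC5A had been knocked out (KO) were kept for 8 h in medium with 0.1% DMSO, 50 µM 7-fluorotryptamine (7FTA, a tryptamine that carries a fluorine atom), 10 ng/mL of the cytokine TNFα, or TNFα and 7FTA together. Each of these 8 groups had 3 libraries, which gives 24 libraries of poly(A)-selected RNA, sequenced as single-end reads on an Illumina NextSeq instrument. Group and replicate number were taken from the sample titles. The labels give a DMSO content for the DMSO groups alone. Whether the other groups contained DMSO is not stated, so a difference in vehicle could not be separated from the treatment effects.

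Per the labels, the deposited table held raw gene counts, 1 column per library. The submitters' processing notes name STAR 2.6.1d, featureCounts 1.6.4, DESeq2 1.20.0 and the genome build GRCh38, without saying which step each served, the strand setting or the annotation release. The values were checked to be whole numbers from 0, with column totals that differ between libraries, and they were used with no further change. The table had 60623 genes, of which 30061 had a count in at least 1 library. Gene positions were taken from GENCODE 29 on GRCh38 by gene identifier.

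Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with filterByExpr on the 8 groups, which left 14059 genes, and TMM factors ran from 0.944 to 1.05. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries with edgeR (robust estimation), and each contrast was tested on both sides with the quasi-likelihood F test. A gene is called changed when its Benjamini-Hochberg adjusted p over the tested genes was under 0.05. Levels are CPM (counts scaled to a common library size with TMM factors), given as mean and SD of 3 libraries. Fold changes are log2 values with a standard error (SE) derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic.

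The comparisons were KO against WT with DMSO, with TNFα and as the mean of the 4 treatments; 7FTA against DMSO, TNFα against DMSO, and TNFα with 7FTA against TNFα alone, each in WT and in KO cells; and 4 differences between such effects, tested as interactions. The comparisons, the tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined, except where a sentence says otherwise. Lists of genes for pathways, cell states and other cell types were tested with camera on voom values at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated for each list, and fry, which asks whether the genes of a list move on balance in 1 direction, were the alternatives. Lists with fewer than 3 tested genes were not tested. Counts of list members are of those called over all genes. For some lists the number called when p is adjusted over the list alone is also given.

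The named genes were GPRC5A, the 10 largest increases and the 10 largest decreases of each comparison between groups, the 5 largest of each sign of each interaction, and the 4 members with the smallest p of the called lists and of 4 lists in any case. The largest changes were taken among called genes with a symbol, a mean log2 CPM of at least 1 and, outside the interactions, libraries of the compared groups that did not overlap. Chance alone gives such separation for 10% of genes with 3 libraries against 3. Not every gene so chosen is printed.

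The steps were tested on simulated data drawn with the mean of each gene over all libraries, equal in every group, and with the dispersions of the libraries. With 100 genes shifted by 0.5 or by 1 on the log2 scale in each case, the 7FTA comparison in WT cells recovered 62% and 88% of them, with 2.6% of the calls false. The interaction of TNFα and genotype recovered 59% and 71%, with 4.41% of the calls false. Beyond the shifted genes, the simulated data held no differences between genotypes or treatments. These shares therefore do not cover data with the large differences seen here. A list with a planted shift was called, and 0 of the other lists among the 26 tested were. Genes were drawn independently of each other in this single draw. It therefore cannot show how often lists whose genes move together are called falsely.

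Total counts per library were between 16782857 and 27247407, and between 18439 and 20513 genes had a count. The common biological coefficient of variation was 4.06%. The 24 pairs of libraries within groups differed by more than counting error (chi-square per degree of freedom 2.07 to 6.63 over genes with at least 20 counts in the pair), so none is a copy of another. The residuals of libraries with the same replicate number in different groups had correlations from -0.0649 to 0.119 (mean 0.0191), and 0 of 28 pairs of groups had all 3 correlations above 0.1. The replicate number was left out of the model and used as a block in an alternative.

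The alternatives were RLE factors in place of TMM, DESeq2, limma-voom, no filter on low counts, a stricter filter (1 CPM in at least 6 libraries), a fit of the compared groups alone, the replicate number as a block, and each library of the compared groups left out in turn. Added after the data were seen were a fit without the 2 libraries that deviate most from their groups, and the KO comparisons without genes on shifted stretches of chromosomes. Such stretches were sought in windows of 50 neighbouring genes with a mean log2 CPM of at least 3, and compared with 1000 shuffles of the gene positions. To see how often other splits of the same libraries give as many called genes, all 10 splits of 3 against 3 libraries were fitted, and 60 drawn splits for the mean genotype comparison and for each interaction. All columns of the table were used.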

Results

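Gene expression was measured by RNA sequencing in 24 libraries of HT-29 cells, WT or KO for GPRC5A, a membrane receptor of class C whose gene is induced by retinoic acid. Each genotype was treated for 8 h with DMSO, 7FTA, TNFα or TNFα with 7FTA, with 3 libraries per group. Total counts per library ran from 19121484 to 26901257 in WT cells with DMSO, from 16975783 to 23384485 with 7FTA, from 17224418 to 19485317 with TNFα and from 17132158 to 21958864 with both. In KO cells they ran from 18356545 to 23488229 with DMSO, from 21319006 to 27247407 with 7FTA, from 16782857 to 22109743 with TNFα and from 19806523 to 23795935 with both. Mitochondrially encoded genes took 0.569% to 1.15% of the counts, the most in replicate 2 of WT cells with TNFα. The first principal component (41.1% of the variance) separated the genotypes, the second (26.8%) the libraries with and without TNFα, and the third (3.7%) those with and without 7FTA. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these libraries. The running numbers in the sample titles put the libraries of each group in a row, and all libraries without TNFα before all those with it, so an effect of processing order could not be separated from the groups or from TNFα. The counting intervals given for ratios cover counting error only.

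GPRC5A (ENSG00000013588, chromosome 12, 12890782 to 12917937, plus strand, GRCh38) was lower in KO cells under every treatment. With DMSO its level was 207 ± 5.84 CPM (SD, n = 3) in WT and 69.8 ± 2.26 CPM (SD, n = 3) in KO cells, a log2 fold change of -1.57 ± 0.04 (SE), or 2.97-fold lower. With 7FTA the levels were 212 ± 1 and 67 ± 2.17 CPM, with TNFα 245 ± 3.64 and 77.9 ± 0.819 CPM, and with both 243 ± 10.2 and 77.9 ± 2.76 CPM (SD, n = 3 each). The lowest WT library had 202 CPM and the highest KO library 80.6 CPM, and 33.7% of the GPRC5A RNA was left in KO cells. Counts of the whole gene do not tell which part of its RNA was left.

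**Figure D1:**
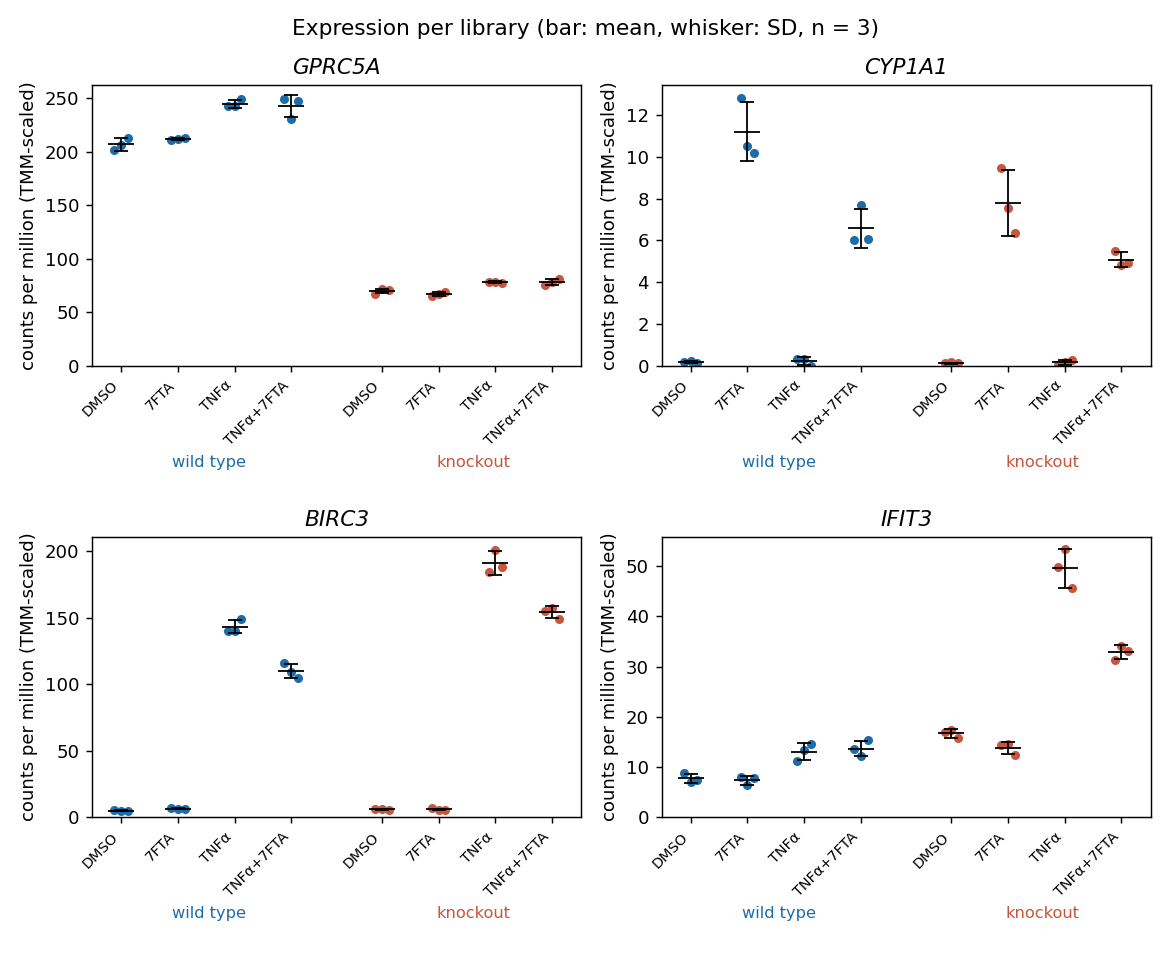
CPM of GPRC5A, CYP1A1, BIRC3 and IFIT3 (vertical axes) in each library of the 8 groups (horizontal axis); bars are means and whiskers SDs of 3 libraries. GPRC5A was at 202 CPM or more in every WT library and at 80.6 CPM or less in every KO library.

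The comparison of KO with WT cells in DMSO asks what differs between the genotypes without treatment. The sample titles name no separate KO clones, so loss of GPRC5A cannot be separated here from other differences between the WT and KO cells. Genes of secretory epithelium were among the largest differences: REG4, a lectin of secretory cells of the gut (chromosome 1, 119794018 to 119811660), was higher by 3.10 ± 0.06 (log2, SE), 8.60-fold, and MUC5AC, a gel-forming mucin (chromosome 11, 1157953 to 1201138), by 3.16 ± 0.25, 8.96-fold. CXCR4, a chemokine receptor (chromosome 2, 136114349 to 136118165), was 13.4-fold higher (3.75 ± 0.13) and NUPR1, a stress-induced chromatin protein (chromosome 16, 28532708 to 28539174), 13.8-fold (3.79 ± 0.20). Other large increases were NEBL (18.5-fold), PLCB4 (14.0-fold), SUCNR1 (11.6-fold) and ST6GAL1 (9.5-fold). TAGLN3 was 21.1-fold lower in KO cells (-4.40 ± 0.44), WNT11, a secreted Wnt ligand (chromosome 11, 76186325 to 76210736), 9.84-fold lower (-3.30 ± 0.08), TMEM158 9.95-fold, FBN2 8.08-fold and HSD3B1 6.77-fold lower (n = 3 libraries per group throughout).

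Of the goblet and secretory cell markers, 15 were higher, 6 lower and 1 not called (median log2 difference 1.36; adjusted p = 0.000174 by camera, 0.0186 as adjusted p with an estimated correlation). AGR2, a secretory-pathway disulfide isomerase, was higher by 1.76 ± 0.04 and CREB3L1 by 1.43 ± 0.05, while WFDC2 was 3.54-fold lower. All other list calls of this comparison were lost with an estimated correlation. Interferon-stimulated genes were higher for 35 of 41 members and lower for 0, with 6 not called (median 0.94; adjusted p = 4.45e-13; adjusted p = 0.178 with an estimated correlation), and 36 were higher when adjusted over the list alone. They included ISG15, a ubiquitin-like modifier (0.86 ± 0.06), ISG20 (1.67 ± 0.11) and OASL (1.14). Of 17 genes of MHC class I antigen presentation, 14 were higher and 1 lower (adjusted p = 9.41e-06; adjusted p = 0.141 with an estimated correlation), or 16 and 1 adjusted over the list alone. TAP1, a subunit of the peptide transporter, was 2.27-fold higher (1.19 ± 0.08). Of 40 TNF and NF-kB target genes, 3 were higher and 19 lower (adjusted p = 0.0137; adjusted p = 0.19 with an estimated correlation), or 4 and 19 adjusted over the list alone. PTGS2, which makes prostaglandins, was lower by -1.51 ± 0.07.

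Absorptive enterocyte markers were higher for 9 and lower for 3 of 13 (adjusted p = 0.0137; adjusted p = 0.19 with an estimated correlation), among them DPP4 (1.49) and VIL1 (0.72). NRF2 targets were higher for 16 and lower for 4 of 25 (adjusted p = 0.000447; adjusted p = 0.234 with an estimated correlation), with AKR1B10 at 2.06 and AKR1C1 at 1.42. Hypoxia-inducible genes were higher for 11 and lower for 2 of 22 (adjusted p = 0.033; adjusted p = 0.41 with an estimated correlation), and chaperones of the endoplasmic reticulum for 8 and 1 of 20 (adjusted p = 0.00265; adjusted p = 0.205 with an estimated correlation). Retinoic acid targets were lower for 8 and higher for 3 of 13 (adjusted p = 0.00857; adjusted p = 0.062 with an estimated correlation); TGM2, a transglutaminase, was 4.74-fold lower and RARRES1 2.68-fold. Cholesterol genes were lower for 13 and higher for 2 of 25 (adjusted p = 0.01; adjusted p = 0.234 with an estimated correlation), p53 targets lower for 9 and higher for 3 of 21 (adjusted p = 0.0437; adjusted p = 0.141 with an estimated correlation), and immediate-early genes lower for 17 and higher for 6 of 34 (adjusted p = 0.0437; adjusted p = 0.41 with an estimated correlation). The lists not called were the aryl hydrocarbon receptor (AhR) targets (2 higher, 5 lower), ATF4 targets (10 and 12, median -0.17 and mean 0.12), cell-cycle genes (4 and 9), cAMP-responsive genes (2 and 2), Wnt targets (7 and 9), tight junction genes (14 and 5), mesenchymal genes (2 and 6), apoptosis regulators (12 and 11), tryptamine and serotonin genes (4 and 3), mitochondrially encoded genes (0 and 1), nuclear respiratory chain genes (4 and 6), histones (1 and 0), immune markers (0 and 2) and endothelial markers (2 and 0). In all, 6763 genes were called, 3374 higher and 3389 lower in KO cells, of which 969 by at least 2-fold.

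With TNFα, KO and WT cells differed with the smallest list p in the interferon-stimulated genes. Of these, 40 were higher in KO cells, 0 lower and 1 not called (median 1.52; adjusted p = 1.99e-34, 0.0215 as adjusted p with an estimated correlation), and 41 were higher when adjusted over the list alone. OAS2, an antiviral enzyme that senses double-stranded RNA (chromosome 12, 112978395 to 113011723), was 8.50-fold higher (3.09 ± 0.12, SE, n = 3) and IFIT3 was higher by 1.91 ± 0.09. All 17 antigen presentation genes were higher (adjusted p = 1.85e-13, 0.0215 as adjusted p with an estimated correlation). The secretory markers were higher for 13 and lower for 3 (adjusted p = 0.00114, 0.0217 as adjusted p with an estimated correlation). The calls of 9 further lists were lost, at values from adjusted p = 0.0938 to adjusted p = 0.315 with an estimated correlation, NF-kB targets (12 higher, 20 lower) among them. CXCR4 was 14.2-fold and PLCB4 14.3-fold higher, and FBN2 12.9-fold and WNT11 10.8-fold lower. Here 7115 genes were called, 3590 higher and 3525 lower. Called with DMSO as well were 5393, of which 5364 in the same direction; 2658 were higher in both, against 862 for independent lists. Across genes, which are not independent replicates, Pearson's r of the differences was 0.811 and Spearman's rho 0.782, and r was 0.207 without the filter on low counts.

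Over the mean of the 4 treatments, 9992 genes were called, 5108 higher and 4884 lower in KO cells, with GPRC5A at -1.63. All 41 interferon-stimulated genes were higher (median 1.11; adjusted p = 6.43e-18; adjusted p = 0.0991 with an estimated correlation), and the calls of the other lists were lost in the same way. Windows of 50 neighbouring genes, chosen after the values were seen, showed whole stretches of chromosomes with lower expression in KO cells: 18 of 185 windows had a median of at least 0.2 from 0, each below it, against 0 in any of 1000 shuffles of gene positions. They formed 6 stretches, on chromosome 6 (148272304 to 170584692, median -0.46), chromosome 8 (406428 to 86478420, -0.46), chromosome 9 (121038 to 93679587, -0.25, and 124257606 to 134068535, -0.22), chromosome 13 (19633681 to 114337626, -0.48) and chromosome 19 (21020620 to 58599801, -0.30). The ends of these stretches follow from the limit of 0.2 and from the windows. The other windows of chromosome 8 (medians -0.12 to -0.20) and of chromosome 9 (-0.11 to -0.16) were also below 0 under all 4 treatments. All tested genes off the stretches had a median of 0.03. None of the 6 comparisons between treatments had such a window. Of 1459 tested genes on these stretches, 971 were called lower and 204 higher. Without them 5767 genes were called with DMSO, 6102 with TNFα and 8807 over the mean. The list tests of KO against WT cells were not repeated without these genes. How far the stretches contribute to lists lower in KO cells was therefore not tested.

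**Figure D2:**
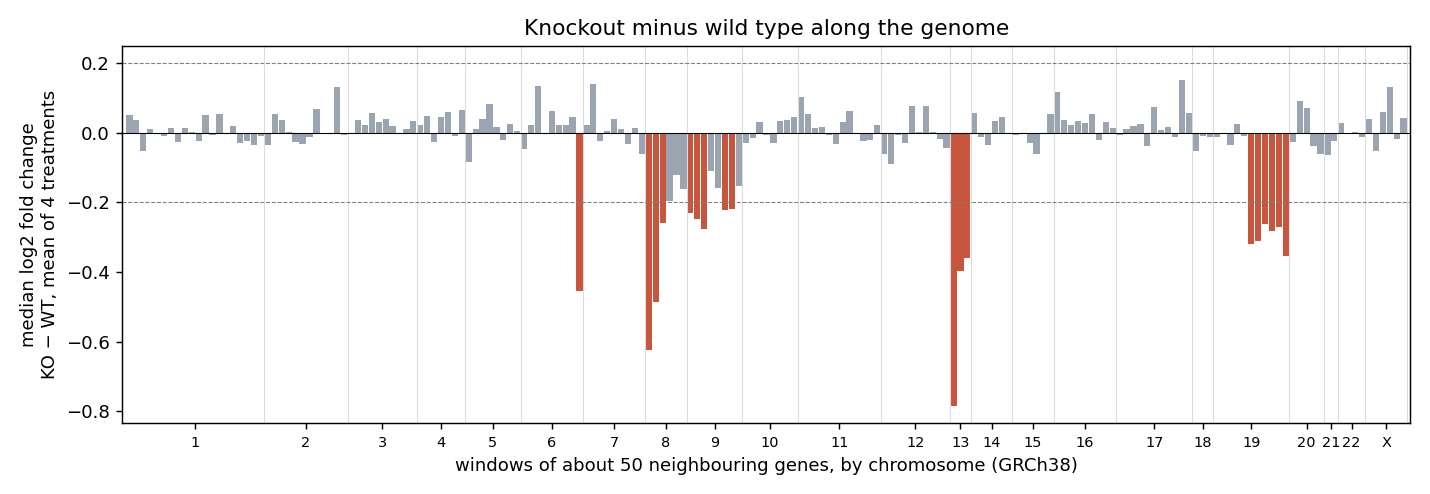
Median log2 fold change of KO minus WT cells, mean of the 4 treatments (vertical axis), in windows of about 50 neighbouring genes along the chromosomes (horizontal axis). The 18 windows at least 0.2 from 0 (dashed lines) are red and lie below 0.

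The comparison of 7FTA with DMSO asks what this tryptamine does to the cells. Genes of the AhR, a receptor for planar aromatic compounds, were among the largest increases in both genotypes. CYP1A1, a monooxygenase (chromosome 15, 74719542 to 74725610), had 707 counts with 7FTA against 11 with DMSO over 3 WT libraries each, a depth-scaled ratio of 72.3 (95% counting interval 40.2 to 146), and 600 against 8 counts in KO cells, a ratio of 60.9 (30.7 to 142). CYP1B1 (chromosome 2, 38066973 to 38109902) rose from 6.6 ± 0.312 to 23.4 ± 0.911 CPM in WT (SD, n = 3; 3.55-fold) and from 7.36 ± 0.777 to 30.9 ± 1.45 CPM in KO cells (4.17-fold). ALDH1A3, an enzyme that makes retinoic acid, rose by 1.49 ± 0.09 and 1.52 ± 0.10 on the log2 scale (SE), and the peptide hormone receptor VIPR1 2.02-fold in WT and 2.40-fold in KO cells. The adhesion receptor ADGRF1 rose 2.58-fold and 3.10-fold. Among the decreases were IFI44L in WT cells (2.50-fold), the metallothionein MT1G in WT cells (1.81-fold), the chemokine CX3CL1 in KO cells (2.89-fold) and IFIT1 in both (1.61-fold and 1.46-fold). A value for a single genotype does not mark a difference: the interaction test of this 7FTA effect called 0 genes.

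Of 12 AhR targets, 8 rose in WT and 9 in KO cells and 0 fell (adjusted p = 2.25e-25 and 1.21e-30, against 3.16e-06 and 7.26e-07 as adjusted p with an estimated correlation); adjusted over the list alone, 8 and 10 rose. Cholesterol synthesis and uptake genes rose for 11 and 13 of 25, and 0 fell (adjusted p = 5.53e-25 and 2.05e-22, against 0.000119 and 0.000225 as adjusted p with an estimated correlation; 20 and 17 adjusted over the list alone). The mevalonate pathway enzyme MVD rose by 0.42 ± 0.05 and 0.28. NRF2 targets rose for 9 of 25 in each genotype, among them the ferritin chain FTH1 (0.31 ± 0.03 and 0.23) and GCLM of glutathione synthesis (0.27 and 0.25), and 0 fell (adjusted p = 3.44e-20 and 3.83e-21, against 0.00647 and 0.00399 as adjusted p with an estimated correlation; 12 and 15 adjusted over the list alone). Cell-cycle genes fell for 5 and 10 of 31 (adjusted p = 3.07e-08 and 1.37e-18, against 0.0368 and 0.00135 as adjusted p with an estimated correlation), with the helicase subunit MCM7 at -0.14 and -0.18. Antigen presentation genes rose for 4 and 3 of 17 (adjusted p = 7.47e-08 and 4.4e-07); the call held in WT (0.0474) and was lost in KO cells at an adjusted p = 0.0567 with an estimated correlation. Chaperones of the endoplasmic reticulum rose for 1 and 5 of 20 (adjusted p = 0.000938 and 1.19e-10; adjusted p = 0.253 with an estimated correlation in WT and 0.00957 in KO cells). Interferon-stimulated genes fell for 2 and 4 of 41 (adjusted p = 0.000215 and 5.09e-06; adjusted p = 0.478 and 0.428 with an estimated correlation). ATF4 targets rose for 2 and 1 of 27 (adjusted p = 0.0162 and 0.00792; adjusted p = 0.402 and 0.412 with an estimated correlation). TNF and NF-kB targets were not called (2 rose in WT and 1 fell in KO cells; adjusted p = 0.216 and 0.504).

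In WT cells 288 genes were called with 7FTA, 203 up and 85 down, 18 of them by at least 2-fold. In KO cells the counts were 335, 204 up and 131 down, with 17 by at least 2-fold. Called in both were 145, all in the same direction, and 116 rose in both, against 2.95 for independent lists. Across all tested genes, most of them not called, Pearson's r was 0.316 and Spearman's rho 0.291. Without the filter on low counts r was 0.0177. Without replicate 1 of WT cells with 7FTA, 190 genes were called. In KO cells the count was 197 without replicate 2 and 222 without replicate 3 of the DMSO group, and 220 without replicate 1 and 211 without replicate 2 of the 7FTA group.

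TNFα, a cytokine that acts through the transcription factor NF-kB, was compared with DMSO to give the inflammatory response of each genotype. IL32, a cytokine (chromosome 16, 3065297 to 3082192), rose from 0.477 to 64.9 ± 4.92 CPM (SD, n = 3) in WT and from 0.594 to 73.4 CPM in KO cells, 137-fold and 119-fold. CXCL8, which attracts neutrophils, rose from 23.2 ± 3.07 to 1030.0 ± 21.5 CPM and from 11.2 ± 0.995 to 748 ± 45 CPM (SD, n = 3). BIRC3, an inhibitor of cell death (chromosome 11, 102317450 to 102339403), rose 28.3-fold and 32.0-fold. CXCL10, a chemokine for T cells (chromosome 4, 76021117 to 76023497), rose 33.5-fold and 75.9-fold. Among the largest decreases were CD200, a ligand that restrains immune cells (4.19-fold in WT, 2.85-fold in KO cells), the stem cell factor ASCL2 in WT cells (4.06-fold), and MT1G (4.0-fold) and ATOH1, the factor that specifies secretory cells (2.51-fold), in KO cells. A value for a single genotype does not by itself mark a difference between the genotypes, which the interactions below test.

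Of 40 TNF and NF-kB targets 39 rose and 0 fell in each genotype (medians 2.61 and 2.56; adjusted p = 2.44e-49 and 6.35e-57, against 2.64e-07 and 9.86e-08 as adjusted p with an estimated correlation). All 17 antigen presentation genes rose in both (adjusted p = 1.08e-20 and 1.47e-33, against 0.00164 and 0.000113 as adjusted p with an estimated correlation), with TAP1 at 3.07 ± 0.07 and 3.17 ± 0.06. Interferon-stimulated genes rose for 36 of 41 in WT (median 0.70; adjusted p = 3.55e-15; adjusted p = 0.0963 with an estimated correlation) and for 40 in KO cells (median 1.57; adjusted p = 4.37e-52, 0.00142 as adjusted p with an estimated correlation). Cell-cycle genes fell for 27 and 30 of 31, and 0 rose (adjusted p = 2.78e-14 and 5.97e-20, against 0.00375 and 0.000705 as adjusted p with an estimated correlation). Apoptosis regulators rose for 19 and 23 of 35 and fell for 1 and 0 (adjusted p = 5.05e-07 and 1.34e-12, against 0.00375 and 0.000199 as adjusted p with an estimated correlation); the protective CFLAR (0.89 in WT cells) and the death ligand TNFSF10 (2.43 in KO cells) were both among them. Calls lost with an estimated correlation were those of the chaperones (14 of 20 rose in WT and 12 in KO cells; adjusted p = 0.052 and 0.0983 with an estimated correlation), NRF2 targets (14 and 13 of 25; 0.324 and 0.317) and immediate-early genes (19 and 15 of 34; 0.173 and 0.317). In KO cells secretory markers fell for 11 and rose for 3 of 22 (adjusted p = 0.0143; adjusted p = 0.0734 with an estimated correlation), REG4 by -0.76 and the secretory factor SPDEF by -0.97. In WT cells 5395 genes were called (2740 up, 2655 down, 604 by at least 2-fold), and in KO cells 4340 (2259 up, 2081 down, 527 by at least 2-fold). Called in both were 3394, of which 3377 in the same direction; Pearson's r across genes was 0.763 (0.15 without the filter on low counts) and Spearman's rho 0.663.

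**Figure D3:**
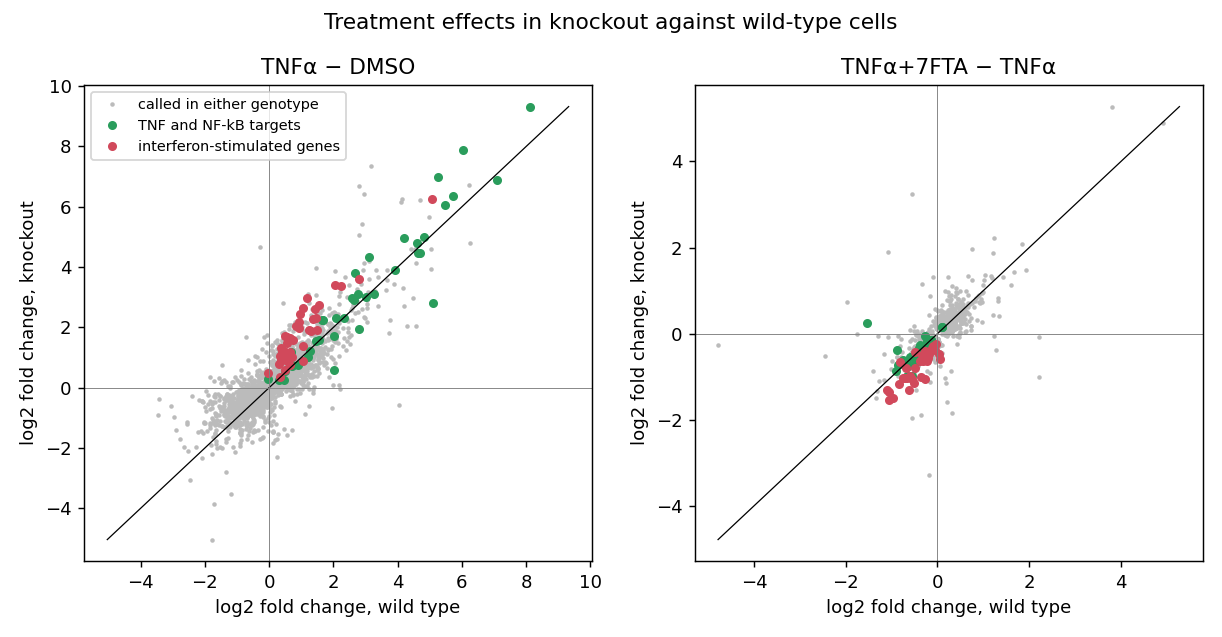
Log2 fold change in KO (vertical axes) against WT cells (horizontal axes) for TNFα against DMSO and for TNFα with 7FTA against TNFα. Each point is 1 gene called in at least 1 genotype for that comparison, and other genes are not shown. NF-kB targets are green, interferon-stimulated genes red, and the line is that of equality. Over all tested members, shown or not, the interferon-stimulated genes had a median of 0.70 in WT and 1.57 in KO cells with TNFα.

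Adding 7FTA to TNFα asks whether the compound changes the inflammatory response. IL32 fell from 64.9 ± 4.92 to 38.5 ± 2.03 CPM in WT and from 73.4 ± 0.851 to 48.2 ± 2.28 CPM in KO cells (SD, n = 3), the neutrophil chemokine CXCL3 1.86-fold in WT and 1.82-fold in KO cells, and CXCL10 1.53-fold in WT and 2.47-fold in KO cells. The antiviral genes MX2 (2.09-fold in WT, 2.92-fold in KO), TRIM22 (2.49-fold and 2.53-fold) and XAF1 (2.16-fold and 2.47-fold) fell too. CYP1B1 rose 3.16-fold and 2.71-fold, the aldehyde dehydrogenase ALDH3A1 2.70-fold and 2.50-fold, and ACSS2, which makes acetyl-CoA, 3.02-fold and 2.17-fold. CYP1A1 had 365 against 11 counts in WT cells, a ratio of 31.1 (95% counting interval 17.2 to 62.8), and 345 against 10 in KO cells, a ratio of 30.6 (16.4 to 64.4).

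TNF and NF-kB targets fell for 23 of 40 in each genotype, and 0 rose in WT and 2 in KO cells (medians -0.24 and -0.27; adjusted p = 2.6e-29 and 2.61e-22, against 1.06e-05 and 2.18e-05 as adjusted p with an estimated correlation); adjusted over the list alone, 29 and 27 fell and 2 rose in each. Interferon-stimulated genes fell for 21 of 41 in WT (median -0.31; adjusted p = 3.14e-16; adjusted p = 0.117 with an estimated correlation) and for 36 in KO cells (median -0.62; adjusted p = 8.31e-75, 0.000259 as adjusted p with an estimated correlation), or 26 and 37 adjusted over the list alone. Antigen presentation genes fell for 2 and 9 of 17 (adjusted p = 1.36e-05 and 2.83e-13; adjusted p = 0.117 with an estimated correlation in WT and 0.00511 in KO cells). AhR targets rose for 9 of 12 in each genotype (2.86e-05 and 2.18e-05 as adjusted p with an estimated correlation), NRF2 targets for 14 of 25 in each (0.00081 and 0.00141) and cholesterol genes for 18 and 21 of 25 (2.86e-05 and 1.55e-05), and 0 members of these lists fell. The sterol pathway genes FDPS (0.42 and 0.37) and MVD (0.55 and 0.48) were examples. Calls lost with an estimated correlation were Wnt targets in WT cells (3 of 18 fell; adjusted p = 0.304) and, in KO cells, cell-cycle genes (8 fell, 1 rose; adjusted p = 0.323) and secretory markers (3 rose; adjusted p = 0.104).

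**Figure D4:**
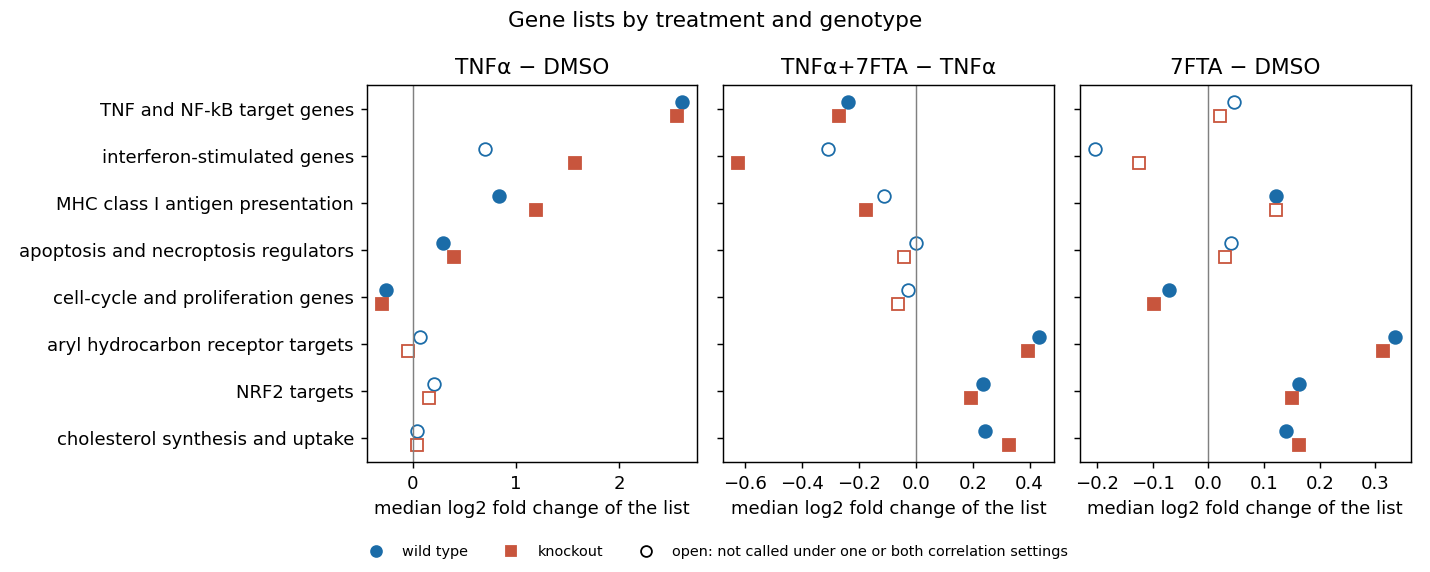
Median log2 fold change (horizontal axes) of 8 gene lists for TNFα against DMSO, TNFα with 7FTA against TNFα, and 7FTA against DMSO, in WT (circles) and KO cells (squares); open symbols mark lists not called under at least 1 of the correlation settings. The NF-kB list stood at 2.61 in WT and 2.56 in KO cells with TNFα, and at -0.24 and -0.27 for 7FTA added to TNFα.

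To keep the fold changes behind the choice of genes apart from the libraries compared, genes that TNFα raised at least 2-fold in the other genotype were followed. The calls came from the fit of all libraries, so the compared libraries shared in its filter and dispersions. Of 392 such genes, 85 fell and 11 rose with 7FTA in WT cells, and 73.0% had a log2 fold change below 0, against 49.3% of other genes. Of 385 in KO cells, 71 fell and 20 rose, with 61.6% below 0 against 50.7%. Over all genes that TNFα raised in the other genotype the differences were smaller: of 2259 genes, 185 fell and 100 rose in WT cells (57.2% below 0 against 48.5% of other genes), and of 2740 genes, 224 fell and 193 rose in KO cells (51.9% against 50.8%). In WT cells 779 genes were called (421 up, 358 down, 36 by at least 2-fold) and in KO cells 1057 (561 up, 496 down, 50 by at least 2-fold). Called in both were 458, all in the same direction, and 209 fell in both, against 12.6 for independent lists. Across all tested genes, most of them not called, Pearson's r was 0.301 and Spearman's rho 0.349. Without the filter on low counts r was 0.00498. In WT cells 503 genes were called without replicate 2 of the TNFα group, and 509 without replicate 3 of the group with both. In KO cells the fit of the compared groups alone called 668, and the fit without the 2 libraries that deviate most 687.

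Whether a treatment acted differently in the genotypes was tested as an interaction. The TNFα effect differed for 499 genes, 288 with a higher and 211 with a lower effect in KO cells, of which 33 by at least 2-fold. Of 41 interferon-stimulated genes 29 had a higher effect in KO cells and 0 a lower one (median difference 0.78; adjusted p = 5.9e-43, 0.0168 as adjusted p with an estimated correlation), or 35 adjusted over the list alone. IFIT3 stood at 7.82 ± 0.9 and 13.1 ± 1.7 CPM without and with TNFα in WT cells, and at 16.7 ± 0.83 and 49.6 ± 3.88 CPM in KO cells (SD, n = 3). Of 17 antigen presentation genes 7 had a higher effect (adjusted p = 7.79e-08; adjusted p = 0.0516 with an estimated correlation), or 9 adjusted over the list alone. NF-kB targets were not called as a list (8 higher, 2 lower, 30 not called; adjusted p = 0.12). The calls of 6 further lists were lost, at values from adjusted p = 0.0516 to adjusted p = 0.367 with an estimated correlation.

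The 7FTA effect without TNFα differed between the genotypes for 0 genes with edgeR, with RLE factors, with DESeq2 and with voom. It differed for 1 gene without the filter on low counts or without replicate 2 of KO cells with DMSO. An unadjusted p under 0.05 was found for 495 genes. This is fewer than the share of 0.05 of the 14059 tested genes that chance gives on average. For CYP1B1 the difference was 0.23 ± 0.12 (log2, SE; 95% interval -0.02 to 0.48). Cell-cycle, chaperone and immune marker lists were called with 0 members past the threshold, and all 3 calls were lost, at values from adjusted p = 0.294 to adjusted p = 0.436 with an estimated correlation. With TNFα present, the 7FTA effect differed for 9 genes, 2 higher and 7 lower in KO cells. An unadjusted p under 0.05 was found for 847 genes, more than the share of 0.05 given by chance. DESeq2 gave 15 and voom 0. Without a single library it was 0 (replicate 1 of WT or replicate 2 of KO cells with TNFα, or replicate 1 of KO cells with both), 1 (replicate 2 of WT cells with TNFα), 4 (replicate 2 of WT cells with both) or 5 (replicate 3 of either WT group). Interferon-stimulated genes had a lower effect for 4 of 41 (median -0.31; adjusted p = 4.83e-23; adjusted p = 0.186 with an estimated correlation), or 16 adjusted over the list alone.

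In WT cells the 7FTA effect with TNFα differed from that without for 39 genes, 11 higher and 28 lower. An unadjusted p under 0.05 was found for 1147 genes, more than the share of 0.05 given by chance. Across all tested genes, Pearson's r between these effects was 0.209 and Spearman's rho 0.224. NF-kB targets had a lower effect for 6 of 40 (median -0.23; adjusted p = 4.7e-17, 0.00029 as adjusted p with an estimated correlation) and 15 adjusted over the list alone, and antigen presentation genes for 3 of 17 (median -0.30; adjusted p = 7.2e-17, 0.00447 as adjusted p with an estimated correlation). The calls of 4 further lists were lost, at values from adjusted p = 0.189 to adjusted p = 0.724 with an estimated correlation. Leaving out replicate 3 of the 7FTA group gave 22 genes, replicate 1 of the group with both 62, and replicate 3 of that group 25.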

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

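Among the tests in this part, the sorting of splits by how they exchange libraries was chosen after the result was seen. Each result below is an effect that differed between groups by an interaction test. The TNFα effect differed between KO and WT cells for 499 genes. It was higher in KO cells for EPSTI1 (1.80 on the log2 scale; on the chromosome 13 stretch lower in KO cells), TRIM22 (1.61), IFI44L (1.61), OAS2 (1.48), HERC6 (1.23), IFI35 (0.74) and BST2 (0.52), which are interferon-induced, and for GSDMB (1.42), TNFAIP2 (0.55) and IER3 (0.50). It was lower for ABAT (-1.54), SPRR1B (-1.48), ETS1 (-1.07) and SDC4 (-0.31), and for IL4I1 (-1.44) and AKAP12 (-1.10), which lie on the stretches of chromosomes 19 and 6 that were lower in KO cells.

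The effect of 7FTA in the presence of TNFα differed between the genotypes for 9 genes. Among them, ADGRF1 (0.66) and EMP1 (0.28) were higher in KO cells, and IFIT3 (-0.65), IFIT5 (-0.51), DDX60L (-0.45), TGFBI (-0.40), PLSCR1 (-0.37) and BST2 (-0.33) lower. In WT cells the 7FTA effect with TNFα differed from that without for 39 genes. AKR1C2 (0.91), AKR1C1 (0.70), ALDH3A1 (0.67), PIGP (0.55) and AKR1B10 (0.53) had a higher effect with TNFα. KRT17 (-0.81), BIRC3 (-0.76), PTGS2 (-0.71), EPHB6 (-0.61) and SDC4 (-0.42) had a lower one, as did AKAP12 (-0.74) and LCN2 (-0.38). AKAP12 and LCN2 lie on the stretches of chromosomes 6 and 9 that were lower in KO cells, but this contrast compares WT libraries alone.

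The larger rise of interferon-stimulated genes with TNFα in KO cells (median difference 0.78) was set beside 3 technical explanations, not all of which could be tested here. With RLE factors the median was 0.779, while that of all tested genes was 0.00101. RLE and TMM factors both hold the median change of all genes close to none, so exchanging them was no test of scaling between libraries. A scaling factor moves all genes of a library alike and leaves the gap between the list and all genes as it is. Leaving out each of the 12 libraries gave medians from 0.722 (without replicate 2 of KO cells with TNFα) to 0.836 (without replicate 2 of KO cells with DMSO), which argues against a single library. With 2 of 41 members on the shifted stretches, copies of these 2 could not carry the median of the list, whatever their values. The 39 members off the stretches had a median of 0.781, which was bound to lie close to that of the list. An effect of the stretches through other genes was not tested. A stronger interferon response to TNFα after the loss of GPRC5A stays open as a hypothesis, as does a trait of the KO line unrelated to GPRC5A, and a further KO clone or GPRC5A put back into the KO cells would test them.

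Labels were exchanged between the groups in 60 drawn splits for each interaction. As many genes as in the real split were given by 5 of 60 for the TNFα effect between genotypes (real 499, highest other 8564), by 6 of 60 for the 7FTA effect with TNFα (real 9, highest other 5557) and by 4 of 60 for the 7FTA effect with against without TNFα (real 39, highest other 3913), so these splits did not exclude chance for these 3. For the 7FTA effect between genotypes (real 0, highest other 5417) 60 of 60 was bound to follow from the count of 0, so the splits say nothing about it. Several splits called many times the real count, which points to a structure of the samples: exchanging most libraries of 1 treatment and not of the other carries the main difference of the groups into the interaction. In the same order, 28, 27, 27 and 29 splits were of that kind, and the highest count among the remaining splits, without the real one, was 260, 0, 5 and 0. As this division was made after the counts were seen, it does not replace the shares above.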

How the results depend on the processing

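The fit without the 2 libraries that deviate most from their groups and the one without the shifted chromosome stretches were chosen after seeing the data. Of the 13 counts of called genes, 13 stayed within 1.5 times with RLE factors and with the stricter filter, 12 with DESeq2 and with voom, 11 with the replicate block and 10 without a filter. The causes of the following differences were not tested. For TNFα with 7FTA against TNFα in KO cells (1057 genes), the fit of the compared groups gave 668 and the fit without the 2 libraries 687. For the 7FTA effect between genotypes (0), no filter gave 1. For that effect with TNFα (9), DESeq2 gave 15, voom 0, no filter 24, the compared groups 2, the replicate block 18 and the fit without the 2 libraries 2. For the 7FTA effect in WT cells with against without TNFα (39), no filter gave 65 and the replicate block 62. With 1 library left out, counts ran from 6105 to 6273 for KO against WT with DMSO, 6374 to 6559 with TNFα and 9851 to 9973 for the mean. They ran from 190 to 219 and from 197 to 233 for 7FTA in WT and KO cells, 4713 to 4931 and 3679 to 3914 for TNFα, and 503 to 717 and 719 to 1085 for 7FTA added to TNFα. For the interactions they ran from 0 to 1, 389 to 473, 0 to 11 and 22 to 62. Of 589 values of named genes, 588 kept direction and call with RLE factors, 586 with DESeq2, 562 with voom and 589 with the replicate block, and none of them reversed. The call was lost for 293 of 5292 values with a library left out and for 21 of 514 with the compared groups alone. Without the 2 libraries it was lost for 16 of 364. These values had been chosen largely for being called in the same libraries, so most were likely to hold. Of 109 list calls, 36 held with an estimated correlation, 90 with fry and 109 with the replicate block. Genes near the detection limit, such as CYP1A1 with DMSO (11 counts over 3 WT libraries), are limited by depth.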

Other observations

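Some tests in this part were chosen after the result was seen. They were the search for shifted windows, the share of called genes on them and the 7FTA score from genes called in WT cells. EREG and AREG, which encode ligands of the EGF receptor, rose with 7FTA by 0.59 and 0.32 in WT and by 0.38 and 0.27 in KO cells (log2), while the immediate-early factor EGR1 changed by -0.33 and -0.36. The immediate-early list as a whole was not called (2 rose and 3 fell in WT, 2 and 2 in KO cells; adjusted p = 0.789 and 0.504). The metallothioneins MT1G, MT1X and MT1E, which bind zinc and copper, fell 1.81-fold, 1.53-fold and 1.48-fold with 7FTA in WT cells. The 7FTA effect without TNFα differed between the genotypes for 0 genes, so this is not a trait of WT cells alone by that test. ITGAM, an integrin chain known from myeloid cells, rose with TNFα from 0.31 ± 0.132 to 8.49 ± 0.216 CPM in WT and from 0.108 ± 0.0509 to 8.6 ± 0.702 CPM in KO cells (SD, n = 3), while the leukocyte marker PTPRC did not exceed 0.173 CPM in any library.

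The stretches of chromosomes 6, 8, 9, 13 and 19 with lower expression in KO cells comprised 18 windows, against 0 in any of 1000 shuffles and 0 in the comparisons between treatments, a pattern that may reflect fewer copies of these stretches in the KO line. After a spline on transcript GC content, length and mean expression was removed, 18 of the 18 windows stayed at least 0.2 from 0, which argues against bias from these properties. The stretches held 11.8% of the genes called over the mean of the 4 treatments. With 1459 tested genes they could not have held most of the 9992 called, so this share decides nothing, and effects of the stretches on genes elsewhere were not tested. RNA counts alone cannot tell fewer copies from silencing of a region, and the loss of GPRC5A cannot be separated from a clone that differs in other ways. Sequencing DNA of both lines would test the hypothesis.

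A second hypothesis was that the 7FTA response follows the amount of GPRC5A RNA, of which 33.7% was left in KO cells. A score from the 458 genes that 7FTA changed in both genotypes with TNFα present, measured in the libraries without TNFα, rose by 0.216 in WT (0.208 to 0.225 over 9 pairs of libraries) and by 0.189 in KO cells (0.163 to 0.212), or 87.9% of the WT value, but these genes had been chosen for a response in KO cells too, so this score excludes nothing. With the 779 genes called in the WT comparison, whether or not called in KO cells, the score rose by 0.161 in WT (0.147 to 0.181) and by 0.134 in KO cells (0.122 to 0.145), or 83.4%. The fold changes behind this choice came from WT libraries, while KO libraries shared in the filter and the dispersions of the fit. The lowest KO pair stood at 75.8% of the WT mean, which argues against a response in proportion to this RNA. The amount of GPRC5A protein was not measured, so a response through the receptor itself stays open.

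For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split (1 of 10 each) called 6763 genes for KO against WT with DMSO and 7115 with TNFα, 335 for 7FTA in KO cells, 5395 and 4340 for TNFα in WT and KO cells and 1057 for 7FTA added to TNFα in KO cells, and the highest other split called 0 in each. For 7FTA in WT cells the real split called 288 and the highest other 1, and for 7FTA added to TNFα in WT cells 779 and 1. For the mean genotype comparison 1 of 60 splits, the real one, called as many genes (9992, highest other 0). A split that mixes the genotypes adds their difference to the spread within groups, so low counts were likely for every other split. These splits therefore do not exclude chance differences between the WT and the KO cells.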
